A study of Mus musculus with 12 samples.

How the data were processed

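Ribosome profiling sequences the stretches of mRNA that ribosomes protect from nuclease. Per the labels' protocols, cells were harvested with cycloheximide at 100 µg/ml, lysates were digested with RNase I, ribosomes were recovered on spin columns, ribosomal RNA was depleted, and fragments between markers of 27 and 30 nt were cloned into small RNA libraries. Libraries were multiplexed and sequenced at 12 samples per lane, per the labels' protocols, and the labels give no sequencing batch. The characteristics name the line 19PP, while the growth protocol says that a reporter-negative subline of it was cultured.

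The authors deposited 1 table of whole-number read counts per library, not normalized, for 22520 versioned Ensembl gene IDs, followed by 5 summary rows. The submitters' processing notes name bcl2fastq 2.16.0.10, Bowtie2 2.3.2, STAR 2.5.3a, HTSeq 0.9.1, DESeq2 1.18.1 and the mouse build mm10, without parameters or roles. The summary rows have the form that HTSeq writes. That reads were counted over coding sequence is stated only in the file naming. Whether strand was used and whether identical reads were collapsed is not given in the sources used here, so intervals and floors cover counting error only, and overlapping genes, antisense genes and near-identical copies may share or lose reads. The summary row for alignments to more than 1 place made up 62.3 to 73.0% of itself and the uniquely aligned reads together. This share of alignments to more than 1 place may count a read once for each of its alignments, so it may not be a share of reads. Reads outside counted features were 18.0 to 34.6% of uniquely aligned reads. Ambiguous reads were 0.524 to 0.677% of uniquely aligned reads. These rows were kept out of library sizes and tests.

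The reference table of gene names held 0 of the Ensembl IDs, so no ID was named. The gene lists chosen by symbol before the data were examined (cell cycle, ribosomal, stress, B cell and other cell type genes) could not be applied, and neither could the rules that named RPL12 and mitotic genes by symbol. Genes were named by the remaining rule, reduced to IDs. It took adjusted p under 0.05, mean CPM of at least 10 in the libraries compared, and libraries of the 2 groups that did not overlap, or for the averaged comparison the same direction in all 3 genotypes. The overlap condition did not apply to differences of the mitotic change. The largest log2 changes were then taken, at most 2 in each direction per comparison, and the text gives some of these.

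Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization). Genes were kept by filterByExpr with a minimum count of 10, leaving 6692 of the 11680 with a read. Genotype and state together formed 6 groups in 1 model, so that groups of 2 shared an estimate of the spread, with a common biological coefficient of variation of 0.0868. The averaged change of state came from a model with genotype and state as separate terms. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and standard errors are the log2 fold change over the square root of its F value. CPM are counts scaled to a common total of the tested genes' reads after TMM scaling, in the usual CPM unit. Log2 CPM for scores and correlations used a prior count of 2. A floor of 3 reads is 5.93 to 11.6 per 1e6 coding reads of a single library. Ratios against 1 to 3 reads, with exact binomial 95% intervals, and bounds against 0 reads use all coding reads of the group without TMM scaling.

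Cell cycle phase was described with the marker gene pairs shipped with scran 1.30.0, which list Ensembl IDs, a choice made after the data were seen. A pair score is the percent of pairs whose first gene exceeds the second, over 9220 G1, 4496 S and 7331 G2M pairs. Lists for camera (limma 3.58.1, preset correlation 0.01) held genes first on balance in 1 phase and second on balance in both others. This definition followed a looser one, every gene first on balance in a phase, which was tried before it and whose values are given with the other alternatives. Adjustment was over 39 tests (3 lists in 13 comparisons). Per-library measures were tested by exact two-sided permutation of state within genotype (216 assignments) or genotype within state (36 assignments). A state score is the mean log2 CPM of the genes called between states in 1 genotype, signed by their direction there and centred over the libraries of the other genotypes.

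The test was checked on simulated counts for 6692 genes with 200 changed genes, drawn from the real means, library sizes and dispersions. For mitotic against asynchronous WT cells, 35% of genes with a log2 change of 1 and 6% with 0.5 were recovered. For the averaged comparison these were 90% and 40%, and for S38D against WT in mitotic cells 34% and 4%. False calls were 4 of 45 for the change in WT cells, 3 of 133 for the averaged comparison, 2 of 40 for S38D against WT and 2 of 20 for the difference of the mitotic change between S38A and WT. A comparison in which nothing changed gave 0 calls. Each setting was drawn once. The real comparisons of state called more genes than were changed here, 1231 in WT cells and 2604 averaged. An adjusted threshold is easier to pass when more genes change, so recovery in those comparisons may differ from these values. Alternatives fixed before the data were examined were DESeq2 size factors, library totals alone, no filter, a mean CPM of at least 10, DESeq2 1.42.0, limma-voom, a replicate block, only the groups compared, and leaving out each library. DESeq2 filters on the mean count and gave no adjusted p to 0 to 6357 of the genes, depending on the comparison. These were left out, not counted as lost. Where a group kept 1 library, it was assumed to vary like the others. Thinning every library to the smallest total (median of 5 draws), the crossed replicate block and those for the cell cycle measures were added after the data were seen.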

Results

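Ribosome footprints were measured in a mouse B cell lymphoma line, 19PP, that carried wild-type (WT) RPL12 or 1 of 2 substitutions at serine 38 of this protein. RPL12, also called uL11, is a protein of the large ribosomal subunit at the base of the stalk that contacts translation factors. In S38A the serine is replaced by alanine, which cannot be phosphorylated, and in S38D by aspartate, whose charge resembles that of a phosphorylated serine. Cells of each genotype were harvested while growing asynchronously or after 8 hr in 100 ng/mL nocodazole, a drug that blocks spindle assembly, followed by 10 min in fresh medium. These 6 groups had 2 libraries each, 12 in all. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. They also do not say how many clones represent a genotype, so a difference between genotypes here is a difference between the cells labelled with them.

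Each library held between 258354 and 505500 reads in coding sequence, and between 9313 and 9818 of the 22520 gene IDs had at least 1 read. Tests covered 6692 genes. A footprint level combines the amount of an mRNA with its translation, and RNA-seq of the same cells was not analysed here, so the values are not translation efficiencies. Between the 2 libraries of a group, log2 CPM over 2518 well-covered genes correlated at 0.934 to 0.967 across genes, which are not independent replicates. Libraries of every group differed by more than sampling noise, with a chi-square per degree of freedom of 1.06 to 1.90. The files do not pair the gene IDs with names, so genes are given by ID and the level of RPL12 itself was not located.

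The change of state was compared first, to see which genes had more or fewer footprints in mitotic than in asynchronous cells. Every library labelled mitotic, and no asynchronous one, came from cells given nocodazole and then fresh medium. Effects of cell cycle state and of this treatment therefore cannot be told apart. ENSMUSG00000021250.13 had the largest rise under the naming rule in each genotype (averaged adjusted p = 1.01e-25, edgeR quasi-likelihood test). It had 0 reads in both WT asynchronous libraries and 173.8 ± 18.1 CPM (SD, n = 2) in WT mitotic libraries, at least 32.4-fold higher against a floor of 3 reads over the group. In S38A cells it had 1 read in the asynchronous libraries together and 269 ± 1.19 CPM (SD, n = 2) in mitotic libraries. In S38D cells the gene went from 6.40 ± 0.346 to 191.6 ± 11.9 CPM (SD, n = 2 each). ENSMUSG00000026360.9 rose from 6.93 ± 4.27 to 137 ± 4.09 CPM in WT cells, from 11.7 ± 1.77 to 178 ± 7.07 CPM in S38A cells and from 10.6 ± 2.44 to 114 ± 32.0 CPM in S38D cells (SD, n = 2 each). Its log2 change averaged over genotypes was 3.77 ± 0.23 (SE, adjusted p = 2.49e-20, edgeR quasi-likelihood test).

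Among genes that fell, ENSMUSG00000040270.16 had 19.7 ± 0.252, 28.3 ± 7.97 and 26.2 ± 15.1 CPM in asynchronous WT, S38A and S38D libraries. It had 2.97 ± 0.539, 1.17 ± 1.65 and 3.82 ± 5.40 CPM in the mitotic ones (SD, n = 2 each). The averaged log2 change was -3.17 ± 0.53 (SE, adjusted p = 2.14e-06, edgeR). ENSMUSG00000074141.13 fell as well, by 2.32 on the log2 scale (SE 0.41, adjusted p = 6.34e-06, edgeR). Its levels were 33.9 ± 3.69, 35.7 ± 4.79 and 28.4 ± 12.0 CPM in asynchronous libraries and 1.30 ± 1.83, 9.50 ± 9.68 and 7.17 ± 4.74 CPM in mitotic ones, in the same order of genotypes (SD, n = 2 each). Both of these genes had under 20 reads in any single library. DESeq2 gave no adjusted p for the former in S38A cells or for the latter in WT cells.

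Averaged over genotypes, 2604 of the 6692 genes passed the threshold, 1266 higher and 1338 lower in mitotic libraries. Of these, 235 were at least 2-fold higher and 255 at least 2-fold lower. The separate comparisons called 1231 genes in WT cells (611 higher, 620 lower), 1246 in S38A cells (604 higher, 642 lower) and 1435 in S38D cells (708 higher, 727 lower). Neither direction clearly outweighed the other. Libraries were scaled to a common total, and the median log2 change of all genes tested was -0.0145 averaged over genotypes. This balance is therefore relative and cannot show whether total footprints per cell changed. Library totals gave 640 higher and 613 lower in S38A cells, and DESeq2 size factors gave 774 higher and 667 lower in S38D cells. In WT cells and in the averaged comparison the balance turned only on leaving out a library, in 1 of 4 and 4 of 12 fits. DESeq2 called fewer in each of the 3 genotypes, with 604, 557 and 719 genes. Leaving out 1 library at a time gave 647 to 959, 702 to 840 and 782 to 1276 genes, with the lowest values without WT asynchronous replicate 2, S38A asynchronous replicate 1 and S38D mitotic replicate 2.

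**Figure D1:**
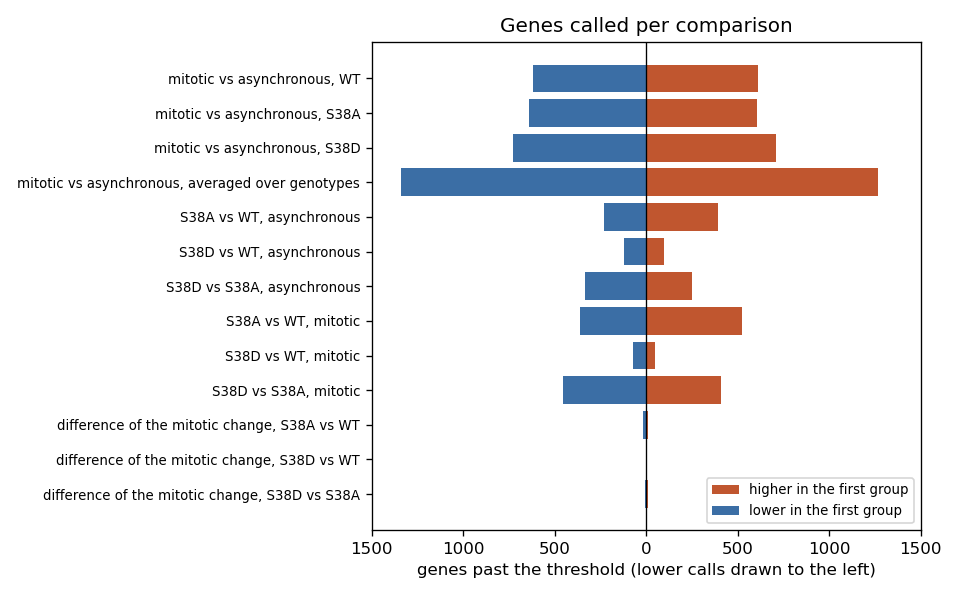
Number of genes past the threshold in each of the 13 comparisons, with genes higher in the group named first drawn to the right and lower ones to the left. For a difference of the mitotic change, higher means a larger log2 change in the genotype named first. The averaged comparison of states has 1266 higher and 1338 lower genes, and the differences of the mitotic change have 30, 4 and 16 genes in all.

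The calls overlapped between genotypes. WT and S38A cells shared 334 higher and 310 lower genes, where independent lists of these sizes would share 55.1 and 59.5. WT and S38D cells shared 391 and 386, against 64.6 and 67.4, and S38A and S38D cells 342 and 352, against 63.9 and 69.7. Calls in all 3 were shared by 266 higher and 252 lower genes, and 11 genes were called in opposite directions in any 2 genotypes. Of the 611 genes higher in mitotic WT cells, 569 had the same direction in S38A cells and 580 in S38D cells, with median log2 changes of 0.70 and 0.71. Of the 620 lower genes, 578 and 601 kept the direction, with medians of -0.59 and -0.78. Across all genes tested, the log2 change in WT cells correlated with that in S38A cells at r = 0.593 and with that in S38D cells at r = 0.642. S38A and S38D correlated at r = 0.604. These comparisons share no library, and genes are not independent replicates.

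Cell cycle marker genes were examined through pairs of genes whose order marks a phase, taken from the scran package by gene ID after the data were seen. The G2M pair score is the percent of 7331 pairs in which the gene marking G2 and M phase has more footprints than its partner. It was 56.4 ± 1.88% in asynchronous and 50.8 ± 1.32% in mitotic libraries (SD, n = 6 each). The difference within genotypes was -5.59 percentage points (exact permutation p = 0.00926, the smallest that the 216 assignments allow, two-sided, adjusted p = 0.0139 over 6 measures). It was -4.90 in WT, -6.14 in S38A and -5.72 in S38D cells. The G1 score was higher by 7.28 points (exact permutation p = 0.00926, adjusted p = 0.0139), at 37.2 ± 1.44% against 44.5 ± 2.29% (SD, n = 6 each). The S phase score was 47.2 ± 0.588% and 42.6 ± 1.28%, a difference of -4.64 points (exact permutation p = 0.00926, adjusted p = 0.0139). The share of coding reads in the 100 most abundant genes of a library, another of the 6 measures, was 0.698 points higher in mitotic libraries (exact permutation p = 0.0278, adjusted p = 0.0278). In each of the 3 scores, the 6 mitotic libraries lay on one side of the 6 asynchronous ones. The 3 sets of pairs share genes, so the scores are not independent of each other. Whether the pairs mark these phases in footprints of this line was not tested.

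**Figure D2:**
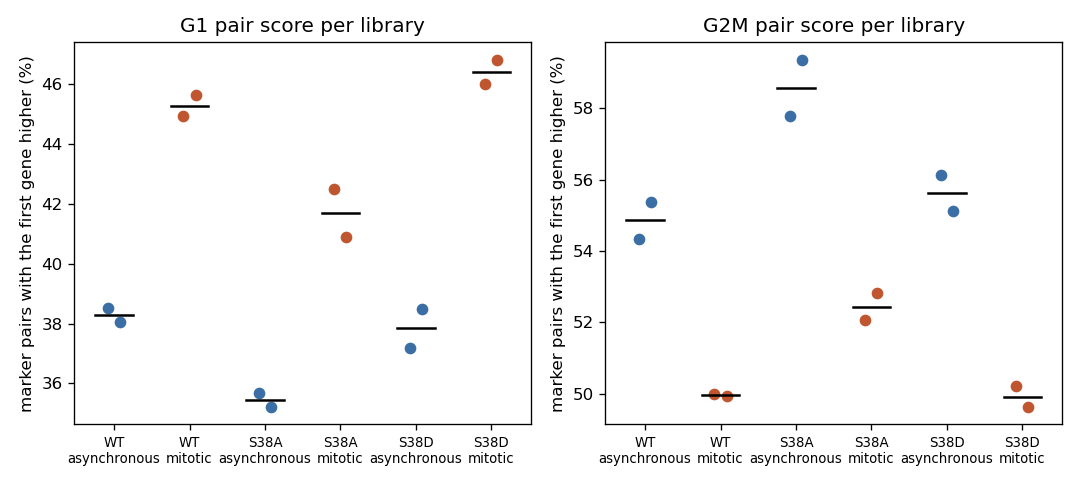
G1 and G2M pair scores, in percent of marker pairs, for each library (points) with the mean of the 2 libraries of a group (bars). Mitotic libraries lie between 40.9 and 46.8% for G1 and between 49.6 and 52.8% for G2M, against 35.2 to 38.5% and 54.3 to 59.4% in asynchronous libraries. The vertical axes do not start at 0.

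The genes that mark G2 and M phase on balance in these pairs, 67 of which were tested, fell as a group in mitotic libraries. Averaged over genotypes, 32 of them were lower, 5 higher and 30 did not pass the gene test, with a median log2 change of -0.35. Camera gave an adjusted p of 0.000132 over 39 tests, and 0.0158 with an estimated correlation. The lists were drawn up after the data were seen. In WT, S38A and S38D cells, 19, 21 and 24 of the 67 were lower and 4, 1 and 2 higher, and the group fell in each (camera adjusted p = 0.00365, 0.000132 and 0.000242). Adjusted over the list alone, 32 were lower and 6 higher in the averaged comparison. Of 74 S phase genes, 24 were lower and 8 higher (camera adjusted p = 0.0370). That call was lost with an estimated correlation (adjusted p = 0.219), as was a fall in S38D cells alone (18 lower, 6 higher, adjusted p = 0.0115 and then 0.210). Of 81 G1 genes, 17 were higher and 9 lower, and the list did not pass (camera adjusted p = 0.218).

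The genotypes were then compared within each state, to see how the substitutions at serine 38 changed footprint levels. ENSMUSG00000045826.8 was nearly absent from both mutants. It had 81.2 ± 6.87 CPM in asynchronous and 92.3 ± 2.27 CPM in mitotic WT libraries (SD, n = 2 each). S38A asynchronous libraries had 0 reads of it, at least 19.3-fold lower than WT against a floor of 3 reads over the group. S38A mitotic libraries had 1 read together, and S38D libraries had 3 reads in asynchronous and 1 in mitotic cells. The asynchronous ratio of WT to S38D was 26.0, with a 95% counting interval of 8.33 to 130.6.

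ENSMUSG00000027562.12 and ENSMUSG00000028931.11 were low in S38A cells and not in S38D or WT cells. The former had 4.23 ± 1.40 CPM in asynchronous and 8.64 ± 0.985 CPM in mitotic S38A libraries. In S38D it had 99.1 ± 0.845 and 215 ± 41.2 CPM, and in WT 78.7 ± 26.9 and 138 ± 24.6 CPM (SD, n = 2 each). The log2 difference of S38D from S38A was 4.41 ± 0.50 in asynchronous and 4.57 ± 0.37 in mitotic cells (SE, adjusted p = 9.48e-10 and 4.94e-15, edgeR). ENSMUSG00000028931.11 had 4.54 ± 2.73 and 1.17 ± 1.65 CPM in S38A, against 59.7 ± 0.217 and 53.2 ± 5.74 CPM in S38D and 63.7 ± 15.0 and 56.9 ± 14.4 CPM in WT libraries (SD, n = 2 each). DESeq2 gave no adjusted p for ENSMUSG00000045826.8 in either mutant against WT, nor for ENSMUSG00000028931.11 between the mutants, so it does not bear on these calls.

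S38A differed from WT in 624 genes in asynchronous cells (392 higher, 232 lower) and in 885 genes in mitotic cells (521 higher, 364 lower). S38D differed from WT in 223 genes (99 higher, 124 lower) and 122 genes (47 higher, 75 lower). Between the mutants, 583 genes differed in asynchronous cells (248 higher and 335 lower in S38D) and 864 in mitotic cells (411 higher, 453 lower). The excess of higher genes in S38A against WT kept its direction under every alternative. It shrank in asynchronous cells to 333 higher and 294 lower with library totals. No alternative measured total footprints per cell, so this excess is relative as well. The balance between the mutants was less firm in mitotic than in asynchronous cells. In asynchronous cells it turned under 1 of 10 alternatives other than leaving out a library, with 269 higher and 233 lower without a filter. In mitotic cells it turned under 6 of 9, with 474 higher and 394 lower under DESeq2 size factors. DESeq2 called 241, 57 and 135 genes in these 3 asynchronous comparisons and 350, 56 and 353 in the mitotic ones. Leaving out S38A asynchronous replicate 1 reduced the S38D to S38A comparison in asynchronous cells to 158 genes and that of S38A with WT to 262. In mitotic cells, leaving out 1 library gave 443 to 550 genes for S38A against WT and 371 to 487 for S38D against S38A, lowest without S38A mitotic replicate 1 and S38D mitotic replicate 2.

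With S38D and WT alone in the fit, 70 genes were called in asynchronous and 228 in mitotic cells. The balance of the calls between S38D and WT depended on the scaling and the filter. With library totals alone, 76 were higher and 160 lower in asynchronous cells and 35 higher and 90 lower in mitotic cells. With DESeq2 size factors, 68 were higher and 64 lower in mitotic cells. Without a filter, 156 were higher and 101 lower in asynchronous cells, and at a mean CPM of at least 10, 66 were higher and 58 lower in mitotic cells. Without WT asynchronous replicate 2 the asynchronous count was 104, and without S38D mitotic replicate 2 the mitotic count was 39.

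The genotype differences recurred between states, which share no library. Across genes, S38A minus WT in asynchronous cells correlated with the same difference in mitotic cells at r = 0.524, and 221 higher and 101 lower genes were called in both, where independent lists of these sizes would share 30.5 and 12.6. For S38D minus WT the correlation was 0.325, with 15 higher and 33 lower genes in both, against 0.695 and 1.39. For S38D minus S38A it was 0.478, with 100 higher and 154 lower genes in both, against 15.2 and 22.7.

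The differences of the 2 mutants from WT are measured against the same WT libraries. In asynchronous cells they correlated at r = 0.564, while unchanged groups set against shared controls gave 0.586 on average over 20 simulations. In mitotic cells the values were 0.385 and 0.489. The covariance was 0.169 in asynchronous and 0.121 in mitotic cells, against 0.0851 and 0.0696 in the simulations. Both mutants shared 51 higher and 66 lower calls in asynchronous cells and 15 and 51 in mitotic cells, where independent lists would share 5.80, 4.30, 3.66 and 4.08. Unchanged groups set against shared controls gave 0 shared calls on average in the asynchronous and 0.05 in the mitotic simulations. These simulations had no changed genes, so they do not show how far shared controls add to the overlap of genes that did change. Between S38A asynchronous and S38D mitotic cells, each against the WT of its own state, no library was shared and r was 0.155. For S38A mitotic and S38D asynchronous cells r was 0.237.

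The G2M marker genes were higher in S38A than in WT cells in both states. In asynchronous cells 13 of 67 were higher and 1 lower, with a median log2 difference of 0.31 (camera adjusted p = 0.000132, and 0.0158 with an estimated correlation). In mitotic cells 16 were higher and 2 lower, with a median of 0.12 (camera adjusted p = 0.00307, and 0.0333 with an estimated correlation). In asynchronous S38D cells 2 were higher than in WT and 0 lower (camera adjusted p = 0.0172). That call was lost with an estimated correlation (adjusted p = 0.0610). The S phase genes were higher in S38A than in WT cells, with 13 higher and 1 lower of 74 in asynchronous and 17 higher and 2 lower in mitotic cells (camera adjusted p = 0.00307 and 0.000299). Neither call held with an estimated correlation (adjusted p = 0.15 and 0.0687). Against S38A, S38D cells had 13 G2M genes lower and 3 higher in asynchronous and 11 lower and 3 higher in mitotic cells (camera adjusted p = 0.0201 and 0.0332). Of the S phase genes, 8 were lower and 1 higher in asynchronous and 18 lower and 2 higher in mitotic cells (camera adjusted p = 0.0315 and 0.000459). With an estimated correlation none of these 4 calls held (adjusted p = 0.0610 and 0.0695 for G2M, 0.297 and 0.0892 for S phase). The G2M pair score was 3.09 points higher in S38A than in WT within states (exact permutation p = 0.0556, the smallest that 36 assignments allow, adjusted p = 0.125 over 18 tests), and differed by -2.73 points between S38D and S38A (same p and adjusted p), so this design could not pass the threshold. At the same p, the share of alignments to more than 1 place differed by -4.85 points between S38A and WT. Between S38D and S38A it differed by 3.97 points. For the share of the 100 most abundant genes these differences were -0.660 and 1.47 points. The marker differences between genotypes were not separated from these differences between libraries.

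Last, the difference between mitotic and asynchronous libraries was compared between genotypes. ENSMUSG00000031004.8 went from 378 ± 70.4 to 584 ± 9.87 CPM in WT cells, from 919 ± 140.1 to 426 ± 52.2 CPM in S38D cells and from 2778 ± 841 to 990 ± 16.3 CPM in S38A cells (SD, n = 2 each). Its log2 change in S38D cells lay below that in WT cells by a difference of -1.72 ± 0.24 (SE, adjusted p = 2.62e-06, edgeR). In all, 30 genes differed in their change between S38A and WT (10 larger, 20 smaller), 4 between S38D and WT (0 larger, 4 smaller) and 16 between S38D and S38A (7 larger, 9 smaller). DESeq2 called 21, 2 and 10, of which 18, 2 and 5 were among the edgeR calls. It gave no adjusted p to 4800, 0 and 6357 of the 6692 genes in these comparisons. The balance moved with the scaling: library totals gave 16 larger and 20 smaller for S38A against WT, and DESeq2 size factors gave 1 and 3 for S38D against WT and 7 and 5 for S38D against S38A. At an unadjusted p under 0.05, 613, 439 and 703 of the 6692 genes passed in edgeR. With no true difference, a share of about 0.05 of the genes would pass in this way. These counts therefore include many genes that chance alone would give. Leaving out single libraries gave 20 to 42, 1 to 14 and 4 to 35 genes, so the last 2 counts rest on individual libraries. In simulated libraries, 18% of genes with a log2 difference of 1 in the change between S38A and WT were recovered, and 0% with 0.5, so most differences of these sizes would be missed in these libraries.

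**Figure D3:**
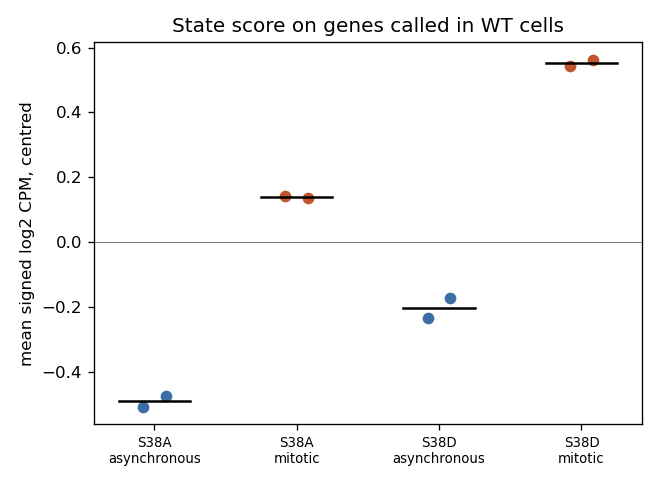
State score of each S38A and S38D library (points; bars are means of 2 libraries) on the genes called between states in WT cells, as mean signed log2 CPM centred over these 8 libraries. Higher values lie toward the mitotic state of WT cells. Group means run from -0.49 in S38A asynchronous to 0.55 in S38D mitotic libraries.

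**Figure D4:**
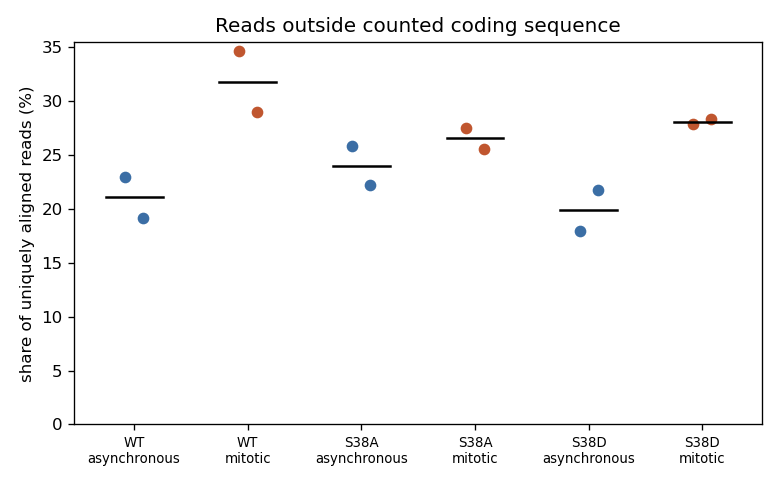
Share of uniquely aligned reads outside counted coding sequence, in percent, for each library (points) with the mean of the 2 libraries of a group (bars). It lies between 18.0 and 25.8% in asynchronous and between 25.6 and 34.6% in mitotic libraries.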

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

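The tests on reads outside the gene counts, and of an explanation for them, were chosen after the results were seen. The change of state differed between genotypes by a direct test of the difference for 30 genes between S38A and WT, 4 between S38D and WT and 16 between S38D and S38A.

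Reads outside the counted coding sequence, which enter no gene test, made up a larger share of uniquely aligned reads in mitotic libraries. The share was 28.8 ± 3.07% in mitotic and 21.7 ± 2.80% in asynchronous libraries (SD, n = 6 each), a difference of 7.17 points within genotypes (exact permutation p = 0.0185, two-sided, adjusted p = 0.0222 over 6 measures). It was 10.7 points in WT, 2.53 in S38A and 8.26 in S38D cells, and these differences were not tested against each other. In S38A cells the libraries of both states overlapped, with 25.8% in an asynchronous and 25.6% in a mitotic library. The number of reads argues against depth as the cause. Mitotic libraries had more uniquely aligned reads than asynchronous ones in WT and S38A cells and fewer in S38D cells (401476 against 610518 on average), where the share was still 8.26 points higher. Whether these reads come from untranslated regions, introns or noncoding RNA was not tested, since the counts give no positions. The share of alignments to more than 1 place, which may count a read more than once, was also higher in mitotic libraries. It differed by 5.88 points (71.2 ± 2.80% against 65.3 ± 2.37%, SD, n = 6 each, exact permutation p = 0.00926, adjusted p = 0.0139).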

How the results depend on the processing

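Thinning, the crossed block and the alternatives for cell cycle measures were chosen after seeing the data. Counts of genes stayed within 1.5 times under both other scalings, the stricter filter and the replicate block. DESeq2 called 604, 557 and 719 genes for the change of state in WT, S38A and S38D cells. It called 241 (S38A to WT), 57 (S38D to WT) and 135 (S38D to S38A) in asynchronous cells and 350, 56 and 353 in mitotic cells. For the difference of the mitotic change it called 2 (S38D to WT) and 10 (S38D to S38A). Without a filter these 2 counts were 7 and 38, after thinning 2 and 9, and limma-voom gave 28 for the latter. Fits of only the groups compared called 70 and 228 genes between S38D and WT in asynchronous and mitotic cells, and thinning left 328 between S38D and S38A in asynchronous cells. The cause was not tested, except that thinning has fewer reads and leaving out a library fewer samples.

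Leaving out single libraries gave 647 to 959, 702 to 840 and 782 to 1276 genes for the change of state in WT, S38A and S38D cells, and 2372 to 2563 averaged. For asynchronous cells the ranges were 262 to 422 (S38A to WT), 104 to 221 (S38D to WT) and 158 to 477 (S38D to S38A), and for mitotic cells 443 to 550, 39 to 60 and 371 to 487. For the differences of the mitotic change they were 20 to 42, 1 to 14 and 4 to 35. In mitotic cells each of the 4 libraries left out moved each genotype comparison by over 1.5 times. Other such moves, by library left out, were as follows. WT asynchronous replicate 2 gave 647 (state, WT), 327 and 104 (S38A and S38D to WT) and 1 (mitotic change, S38D to WT), and replicate 1 gave 14 for the last. S38A asynchronous replicate 1 gave 702 (state, S38A), 262 (S38A to WT) and 158 (S38D to S38A), and replicate 2 gave 406 and 313 for the latter pair. S38D asynchronous replicate 1 gave 7 and 32 (mitotic change, S38D to WT and to S38A), and replicate 2 gave 35 (to S38A) and 388 (S38D to S38A). WT mitotic replicates 1 and 2 gave 817 and 702 (state, WT), and replicate 2 gave 1 (mitotic change, S38D to WT). S38A mitotic replicates 1 and 2 gave 714 and 817 (state, S38A), and replicate 1 gave 4 (mitotic change, S38D to S38A). S38D mitotic replicates 1 and 2 gave 868 and 782 (state, S38D), 1 and 1 (mitotic change, S38D to WT) and 7 and 5 (to S38A).

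The replicate numbers of the titles showed no pairing common to all groups: over 15 pairs of groups the correlation of replicate deviations had a median of -0.0216. Between WT and S38A asynchronous libraries the correlation was 0.122. A pairing of asynchronous libraries, which the main tests would ignore, was not excluded. With the replicate block the averaged comparison called 2559 genes and the differences of the mitotic change 28, 4 and 17. Crossing the numbers of S38D asynchronous libraries, whose deviations correlated at -0.313 with those of WT and -0.193 with those of S38A, called 287 genes against WT and 643 against S38A under the replicate block.

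Of 680 fits of 50 gene and comparison pairs, 594 kept direction and call, 43 lost the call and 0 reversed. The other 43 gave no value, 34 of the 50 in DESeq2 and 9 of 46 with only the groups compared. The pairs were chosen from the main fit as its largest called changes, mostly with no overlap between the libraries of the groups compared. For such pairs, leaving out a library could hardly turn the direction, so the lack of reversals was partly fixed by this choice. For the looser cell cycle lists, the G2M list still fell averaged over genotypes (median log2 -0.18, adjusted p = 0.00239), while the S list was lost there (adjusted p = 0.0731) and for S38D to S38A in asynchronous cells (adjusted p = 0.243). The estimated correlation ended 9 list calls. Over genes at a mean CPM of at least 100, mitotic minus asynchronous pair scores were 11.4 points for G1, -4.03 for S and -11.3 for G2M. Over all genes tested they were 7.28, -4.64 and -5.59 points. The lists fixed by symbol and the cell type markers were not run, for lack of names.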

Other observations

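The tests of sequencing depth and of other splits were set before their results were seen (for the mitotic correlation, after the asynchronous one), and the remaining tests in this part after. Averaged over genotypes, 2604 genes separated mitotic from asynchronous libraries. Of 100 splits of the libraries within genotypes, 1, the real one, gave as many genes, and the highest of the others gave 326. No other split drawn therefore reached this count. The other splits leave the difference of state in the spread within their groups, which lowers their counts. They do not measure how many of the 2604 calls are false. Libraries of a group may come from the same culture, so these splits cannot exclude a chance difference between cultures.

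Libraries labelled mitotic had a lower G2M and a higher G1 pair score than asynchronous ones. Sequencing depth was argued against by thinning every library to the smallest total, after which the G2M difference was -5.49 points. An exchange of the state labels in 1 or 2 genotypes would turn the sign there, and the difference nearest to 0 was -4.90. When each was counted once, 71.6% of the G2M list genes lay lower in mitotic libraries, so the fall was not confined to a few of them. This does not show how far single genes weigh in the pair score, since a gene can enter many pairs. What stays open includes an exchange of labels in all 3 genotypes. It also includes an effect of the library differences that went with state. The share of alignments to more than 1 place, for example, was 5.88 points higher in mitotic libraries. Reduced footprints on these mRNAs in mitosis or after release are open too, which a comparison with mRNA levels could separate. The share of cells in mitosis was not measured in these data. Effects of nocodazole and of fresh medium cannot be told apart from those of state.

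Differences of S38D from S38A went with the mitotic change of WT cells, at r = 0.295 across genes in asynchronous and 0.360 in mitotic libraries. Over 2475 genes at a mean CPM of at least 100, r was 0.496 and 0.553. Differences of S38A from WT went against the mitotic change of S38D cells, at r = -0.222 in asynchronous and -0.307 in mitotic libraries. Those of S38D from WT went with the mitotic change of S38A cells more weakly, at r = 0.108 and 0.140. A state score built on the 1231 genes called in WT cells was -0.49 ± 0.03 in S38A and -0.20 ± 0.04 in S38D asynchronous libraries, and 0.14 ± 0.00469 and 0.55 ± 0.01 in mitotic ones (SD, n = 2 each). On the 1435 genes called in S38D cells, mean scores were -0.45 in S38A and -0.21 in WT asynchronous libraries, and 0.16 and 0.50 in mitotic ones. On the 1246 genes called in S38A cells, they were -0.31 in S38D and -0.38 in WT asynchronous libraries, and 0.41 and 0.28 in mitotic ones. The comparisons correlated here share no library. For S38D against S38A, depth was argued against by thinning, with r = 0.285 in asynchronous and 0.371 in mitotic libraries after it. Fewer S38A cells held by nocodazole would leave asynchronous libraries alike. On the genes called in WT cells, the gap between S38D and S38A there was 0.288, beyond a summed range between replicates of 0.0991. In mitotic libraries the gap was wider by 0.127, barely beyond a summed range of 0.124 chosen as the bound after the values were seen, so fewer held S38A cells may add to it, and a difference between the cell lines of each genotype stays open, untested. So does a difference between libraries. The share of alignments to more than 1 place was 3.97 points higher in S38D than in S38A libraries, and it was higher in mitotic libraries too.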
